A study of Rattus norvegicus with 2 samples.

How the data were processed

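Gene expression in the hypothalamus of male Wistar rats was measured on 2 two-colour oligonucleotide arrays. Animals were 21 days old when they entered the study and were kept singly. Per the labels, 4 animals were used in each of 3 conditions, which were tickling (a hand stimulation that imitates rough play and evokes calls near 50 kHz), a light touch, and no stimulus. Stimulation was given on weekdays for 4 weeks, in cycles of 15 s of rest and 15 s of stimulation. Total RNA was extracted from the hypothalamus, 500 ng was amplified to aminoallyl cRNA, and the product was coupled to Cy3 or Cy5, per the labels' protocols. On both arrays the tickled group was in Cy5. The other dye, Cy3, held the no-stimulus group on one array and the light-touch group on the other. Each comparison therefore had 1 array, with no replicate array and no dye swap. Whether the 4 animals of a condition were pooled, and whether the same tickled RNA was put on both arrays, is not stated.

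The values used were the linear ratios deposited by the authors, 1 per probe and array, given to 2 decimals. The median ratio was 1.00 on both arrays, so the deposited ratios were already centred. Image analysis software, background correction, normalization and the rule that left some probes without a value are not given in the sources used here. The channel in the numerator is not stated either. Cy5 over Cy3, that is tickled over control, is the likely direction, because the labels place the tickled group in Cy5 on both arrays and red over green is the usual form of such a ratio. If the ratio was formed the other way, every ratio above 1 becomes a ratio below 1 and the reverse. Counts above and below 1 then trade places, while sizes and the correlation between the arrays stay as given. Signal levels of the 2 dyes were not used here, so probes could not be filtered or matched on brightness.

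The table held 44290 probes. Of these, 23535 had 1 gene symbol in the platform annotation, 48 had several and 20707 were unnamed in it. Probes with several symbols named no gene. The Entrez identifiers of 23488 probes were found in the RefSeq gene table of the GRCr8 assembly, and 1 symbol changed through it. That table served for names only, and no coordinates were taken from it. Each gene's value was the median log2 ratio of its probes, and 12092 genes had a value on at least 1 array. Of these, 7653 were measured by 1 probe and 4439 by 2 or more.

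With 1 array per comparison there was no test between conditions and no p-value was computed. Genes were counted by size, at a ratio of 2 or more or of 0.5 or less. Precision could be gauged only from probes of the same gene within an array. Their spread was 0.18 log2 units (SD) on both arrays, over 4354 genes on the no-stimulus array and 4226 on the light-touch array. This spread holds probe and hybridisation differences and leaves out variation between animals. The number of arrays, 1 per comparison, limits the precision of every value.

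The light-touch and no-stimulus groups were compared indirectly, as the log2 ratio of the no-stimulus array minus that of the light-touch array. The result stands for light touch over no stimulus only if the same tickled RNA was on both arrays. If it was, the ratios of both arrays also share chance values. Counts of genes past 2-fold on both arrays were therefore set beside the overlap of independent lists and beside 100 simulated data sets in which 3 unchanged arms of equal spread shared the tickled arm. The values of each arm were drawn at random from the observed, centred log2 ratios of both arrays, scaled down and given random signs. The correlation across genes was given with 1000 bootstrap resamples of genes, as a description only, since genes are not independent replicates.

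A set of 30 gene lists was fixed before the data were examined. It covered hypothalamic neuropeptides, opioids, peptide and hormone receptors, monoamine and amino acid transmission, the stress axis, immediate early genes, cell stress, immune and metabolic groups, brain cell types, and markers of tissues that adjoin the hypothalamus. For each list the median log2 ratio was placed among 10000 random lists of the same number of measured genes. Lists were not matched on expression level. A list was said to stand apart when its median lay outside the middle 95% of the random lists, and 3 of the 60 pairs of list and array would do so by chance. Several lists share genes, so these pairs are not independent.

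The genes to be named were also fixed by rule before the data were examined. Among genes with a value on both arrays and a descriptive symbol, the rule took the 10 highest and 10 lowest ratios on each array, the 10 highest and 10 lowest on both arrays by the ratio nearer to 1, the 5 highest and 5 lowest indirect differences, and the highest and lowest member of each list by the mean of both log2 ratios. It also took list members past 2-fold in 1 direction on both arrays, and always Oxt, Avp, Crh, Pomc, Th, Fos, Hcrt, Npy, Agrp, Bdnf and Nr3c1. Other list members given as examples were chosen after their values were seen.

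Alternatives fixed before the data were examined were centring on the array median, scaling both arrays to one spread, using the probe with the largest absolute mean ratio of a gene, keeping only genes with a value on both arrays, thresholds of 1.5-fold and 3-fold, counting probes singly, leaving out genes beyond 3 median absolute deviations from the correlation, and the mean of a list in place of its median. A filter on signal level, also intended, could not be run. After the data were examined, 2 alternatives were added because ratios followed the probe number. One kept only the middle 80% of probe numbers. The other subtracted the median of the 21 by 21 block of probes around each probe, on a layout of 206 rows by 215 columns inferred from the probe numbers, which no source used here states.

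The procedure was tested on simulated data with noise of the within-gene probe spread over 11534 genes, with 50 genes changed at each fold. At a simulated change of 2-fold, 54% of the changed genes were counted, at 3-fold and 4-fold 100% were, and at 1.5-fold 2% were. Of the unchanged genes, 0 were counted. This follows from simulated noise that was normal with 1 SD for all genes. It is no rate of false counts for these arrays, where some probes of a gene differed far more. Lists of 30 genes shifted by 0.15 log2 units stood apart in 100% of 1000 draws, and unshifted lists did so in 4.7%. Those lists were drawn from the same gene values as the range they were set against. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.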

Results

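RNA from the hypothalamus of tickled rats was compared with that of rats given no stimulus on 1 array, and with that of rats given a light touch on another. The no-stimulus array had a value for 30904 of 44290 probes and 11881 genes, and the light-touch array for 30133 probes and 11745 genes. Empty probes made up 30.2% and 32.0%. Both arrays had a value for 11534 genes. There was no replicate array, so no difference below could be set against variation between animals, and values are described by size only. Ratios are given as deposited and are read as tickled over control, which is the likely but unstated direction. Most genes lay close to 1. On the no-stimulus array 98.0% of genes were within 1.5-fold, and on the light-touch array 97.51% were. The SD over genes was 0.20 and 0.22 log2 units, and probes of the same gene on the same array spread by 0.18 log2 units (SD), or 1.13-fold.

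Against no stimulus, which asks how the hypothalamus of a tickled rat differs from that of an unhandled one, the gene value farthest from 1 was that of Ttr, which encodes the thyroid hormone carrier transthyretin. Its ratio was 0.08, or 12.5-fold below 1, and rounding of the deposited value alone allows 11.8 to 13.3-fold. Other low ratios were 0.43 for the vesicular acetylcholine transporter Slc18a3, 0.49 for the choline transporter Slc5a7, 0.35 for the transcription factor Lhx8 and 0.45 for the neurotrophin receptor Ngfr. Among the hypothalamic hormones, gonadotropin-releasing hormone (Gnrh1) had a ratio of 0.38, vasopressin (Avp) 0.508 and oxytocin (Oxt) 0.67. At the other end stood both subunits of thyrotropin. The beta subunit Tshb had a ratio of 9.08 and the alpha subunit Cga, which is shared by the glycoprotein hormones, 7.18.

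In all, 38 genes had a ratio of 2 or more on this array and 12 a ratio of 0.5 or less. After Tshb and Cga, the highest named genes with a value on both arrays began with Chrna3, a subunit of the nicotinic acetylcholine receptor, at 3.99. Next were the odorant receptor Or1j15b at 2.90, Angptl1 at 2.84, Msc at 2.82, Dpf3 at 2.68, Otub2 at 2.66, the D-amino acid oxidase Dao at 2.64 and Smpdl3b at 2.45. The remaining low genes were the splicing factor Prpf31 and Ccdc77, both at 0.42, the thyroid hormone deiodinase Dio3 at 0.427, Lnx1 at 0.497, Lhx6 at 0.50 and the odorant receptor Or1i2 at 0.40. Or1i2 had no value on the light-touch array and was named after its value was seen. Of the other genes fixed in advance, Fos had a ratio of 0.86, Crh 0.85, Th 1.01, Bdnf 1.04 and Nr3c1 1.08. Probes of a gene did not always give like values. The 2 probes of Cga gave 18.7 and 2.76, those of Dio3 gave 0.21 and 0.87, and those of Lnx1 gave 0.24 and 1.03. Avp gave 0.47 and 0.55. Odorant receptors have many similar family members, so the ratio of Or1j15b may hold signal from relatives.

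High ratios on this array depended on where the probe lay in the order of probe numbers. The outermost 20% of probe numbers, 10% at each end, which held 19.2% of the measured probes, held 105 of the 140 probes with a ratio of 2 or more (75%) but 1 of the 28 with a ratio of 0.5 or less (3.57%). All probes of 8 of the 10 highest named genes lay in this outermost 20%. The exceptions were Tshb, and Cga, which had 1 probe in each part. With only the middle 80% of probe numbers, 12 genes had a ratio of 2 or more and 11 a ratio of 0.5 or less. With the local median subtracted, the counts were 27 and 12.

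Hypothalamic neuropeptide and releasing hormone genes stood above other genes as a group on the no-stimulus array, although its members went both ways. Their median log2 ratio was 0.12 over 31 measured members, 19 above 0 and 12 below, where the middle 95% of random lists ran from -0.04 to 0.07. With the middle 80% of probe numbers it was 0.08, with 13 above 0 and 11 below, and still outside the random range. Vasoactive intestinal peptide (Vip) had a ratio of 2.24, cholecystokinin (Cck) 1.94, the melanocortin precursor Pomc 1.62, orexin (Hcrt) 1.38 and Agrp 1.35, against the low values of Gnrh1, Avp and Oxt. Opioid peptides and receptors had a median of -0.14 over 7 members, 5 of them below 0. Its highest member was Pomc and its lowest Oprk1, at 0.76. This median lay inside the random range, at -0.08, once the local median over the array was subtracted. Peptide and hormone receptors had a median of -0.04 over 39 members (-0.07 with the middle 80% of probe numbers), with Npy2r at 0.72 and Insr at 1.56. Genes of GABA and glutamate transmission had a median of -0.06 over 39 members, 25 of them below 0. The GABA synthesis and transport genes Gad1, Gad2 and Slc32a1 were at 0.82, 0.79 and 0.74, while the glutamate transporter Slc17a7 was at 1.64, and the mean of the list was above 0, at 0.03. Heat shock and protein folding genes had a median of -0.06, with 20 of 27 members below 0. Examples are Hspa5 at 0.82 and Hsp90aa1 at 0.86, and the exception Hspa1l at 1.91.

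Markers of tissue around the hypothalamus also stood apart on this array. All 21 measured markers of meninges and connective tissue had a ratio above 1, with a median log2 ratio of 0.20 and values such as 1.32 for the collagen Col1a1 and 1.24 for Aldh1a2. Ependymal and tanycyte markers, from the cells that line the third ventricle, had a median of 0.19 over 11 members, 10 of them above 0, with Rax at 1.52. All 11 pituitary markers lay above 0, with a median of 0.18. Among them growth hormone (Gh1) was at 1.73 and luteinizing hormone beta (Lhb) at 1.13, far below Tshb and Cga. Markers of striatum, cortex and thalamus had a median of 0.19 over 19 members, of which 13 were above 0. The highest were the protein kinase Prkcd at 2.42 and the transcription factor Tcf7l2 at 1.78. Blood and erythroid markers had a median of -0.09 over 9 members, led by the globin genes Hbb-b1 at 0.52 and Hbb at 0.66, whose probes cannot be taken to separate similar globins. Nonneural genes expected near background, such as Ins2 at 1.86, had a median of 0.12 over 12 members. The blood median lay inside the random range, at -0.05, with the local median subtracted, and outside it, at -0.29, with the middle 80% of probe numbers. The nonneural median lay inside, at 0.10, with the middle 80%. The choroid plexus list, which includes Ttr, lay inside the range as deposited, with a median of -0.04 over 14 members, and outside it at -0.10 with the local median subtracted and at -0.11 with the middle 80% of probe numbers.

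**Figure D1:**
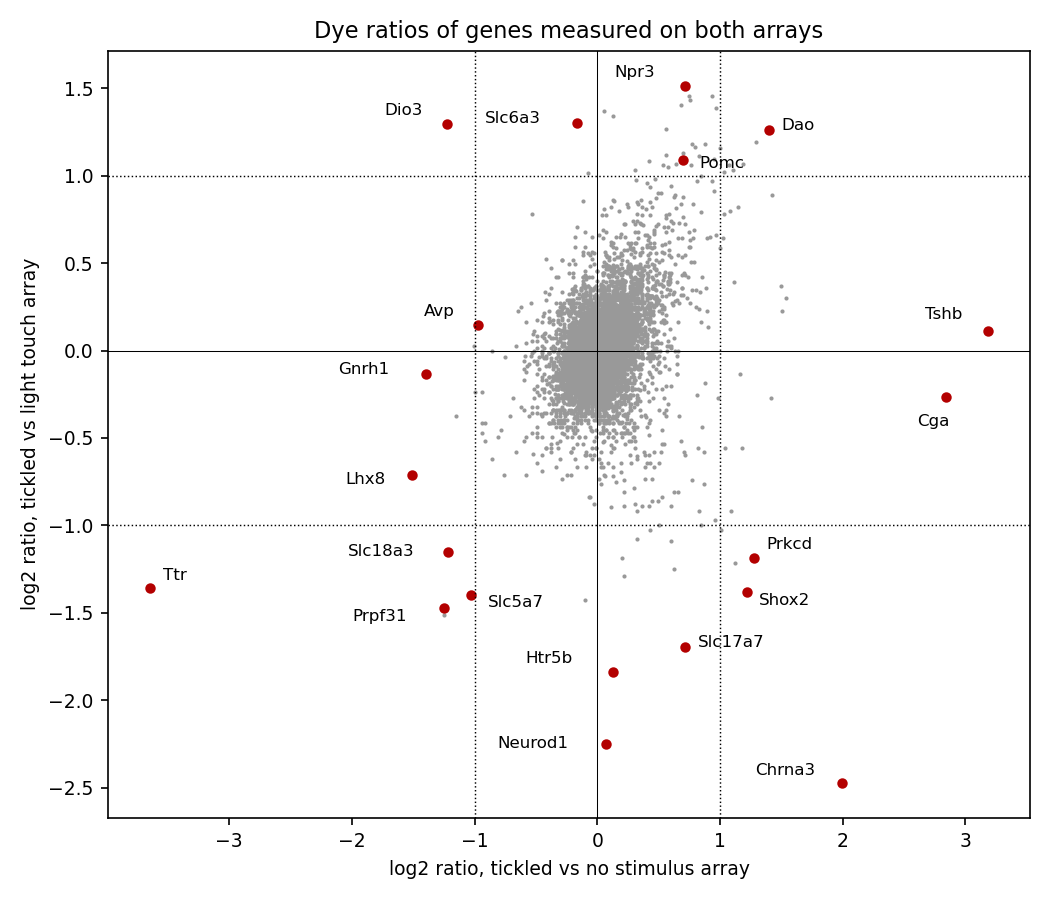
Log2 ratio of each of the 11534 genes measured on both arrays, on the array of tickled against no stimulus (horizontal) and of tickled against light touch (vertical). Grey points are genes, red points are genes named in the text and dotted lines mark a 2-fold ratio. Ttr, at 0.08 and 0.39, is low on both arrays, whereas Chrna3, at 3.99 and 0.18, lies on opposite sides of 1.

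Against light touch, the comparison that keeps human handling and sets apart the kind of stimulation, peptide genes of the hypothalamus mostly had ratios above 1. Pomc had a ratio of 2.13, the appetite peptides Cartpt, Agrp and Npy 1.94, 1.80 and 1.59, melanin-concentrating hormone (Pmch) 1.87 and Hcrt 1.60. The dopamine transporter Slc6a3 had a ratio of 2.47, tyrosine hydroxylase (Th) 1.58 and Tph2, an enzyme of serotonin synthesis, 1.77. Among the 10 lowest named genes with a value on both arrays was Chrna3, which is strongly expressed in the habenula, at 0.18. Others were Neurod1, a transcription factor of pineal and cortical cells, at 0.21, the serotonin receptor Htr5b at 0.28, the cortical and thalamic glutamate transporter Slc17a7 at 0.309, Tph1, the pineal form of tryptophan hydroxylase, at 0.372 and the thalamic transcription factor Shox2 at 0.383.

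Here 41 genes had a ratio of 2 or more and 26 a ratio of 0.5 or less. The highest named genes with a value on both arrays began with Npr3, the natriuretic peptide clearance receptor, at 2.86. Next were Igsf6 at 2.75, Hspa1l at 2.74, the odorant receptor Or2n1i at 2.70, Cnn1 at 2.65, Ier3ip1-ps1 at 2.62, Lama1 at 2.59, Prss27 at 2.54, Slc6a3 and Dio3, at 2.46. Hspa1l, Or2n1i and the pseudogene Ier3ip1-ps1 have close relatives that the probes may not separate. The others were Ccdc77 at 0.35, Prpf31 at 0.36, Slc5a7 at 0.38 and Ttr at 0.39. The probes of Tph1 differed, at 0.73 and 0.19, whereas those of Slc17a7 gave 0.28 and 0.34 and those of Shox2 0.35 and 0.42. Oxt, Avp, Crh, Fos, Bdnf and Nr3c1 had ratios of 1.12, 1.11, 1.25, 0.95, 1.02 and 1.07.

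The outermost 20% of probe numbers held 83 of the 119 probes with a ratio of 2 or more on the light-touch array (69.7%) and 7 of the 51 with a ratio of 0.5 or less (13.7%). All probes of 4 of the 10 highest named genes and of 2 of the 10 lowest lay there. For Cnn1 and Dio3 the only probe with a value on this array also lay there, so that the values of 6 of the 10 highest came from it. With the middle 80% of probe numbers alone, 14 genes had a ratio of 2 or more, with the local median subtracted 23 had, and under either setting 26 had a ratio of 0.5 or less. Of the 26 low genes on this array 5 had several probes, and in 4 of these every probe was at 0.5 or less, while 40 of the 41 high genes had 1 probe. Against no stimulus, 2 of the 12 low genes had several probes, with every probe at 0.5 or less in 0 of them, and 2 of the 38 high genes had several, with every probe at 2 or more in 1.

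Of the 32 neuropeptide and releasing hormone genes measured against light touch, 25 had a ratio above 1 and 9 a ratio of 1.5 or more, with a median log2 ratio of 0.18. The 2 members 1.5-fold or more below 1 were Cck at 0.51 and Nmu at 0.65. The median was 0.22 with the local median subtracted. Opioid peptides and receptors had a median of 0.23, with 7 of 8 members above 0 and prodynorphin (Pdyn) at 1.57. Peptide and hormone receptors had a median of 0.11, with 30 of 37 members above 0, and the dopamine, noradrenaline and serotonin genes a median of 0.12, with 18 of 33 above 0 and both Htr5b and Tph1 below 0.5. Hypothalamic region transcription factors had the highest median of the 30 lists on this array, at 0.30, with 14 of 16 members above 0. Among them Lhx1 was at 1.65, Otp at 1.61, Six6 at 1.53 and Nkx2-1 at 1.48.

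Markers of neighbouring forebrain had the lowest median on the light-touch array, at -0.23 over 19 members, 13 of them below 0. Slc17a7, Prkcd and Lef1 were below 0.5, at 0.309, 0.44 and 0.49. Oligodendrocyte and myelin markers had a median of -0.14, with 17 of 19 members below 0, among them Mbp at 0.891 and Mag at 0.86. Neuron markers had a median of -0.11, with 11 of 18 below 0, of which the neurofilament gene Nefh, at 0.77, was the lowest. The pituitary markers, with a median of 0.15 over 11 members, and the nonneural genes, with the same median over 11, were above the random range. The pituitary median was 0.09 with the local median subtracted and 0.10 with the middle 80% of probe numbers, inside the range both times. With the local median subtracted, blood markers, at -0.20, heat shock genes, at -0.06, interferon and MHC genes, at -0.07, oxidative phosphorylation genes, at -0.04, and meningeal markers, at 0.07, lay outside the range. With the middle 80% of probe numbers, blood markers, at -0.34, and the choroid plexus list, at -0.11, lay below it.

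**Figure D2:**
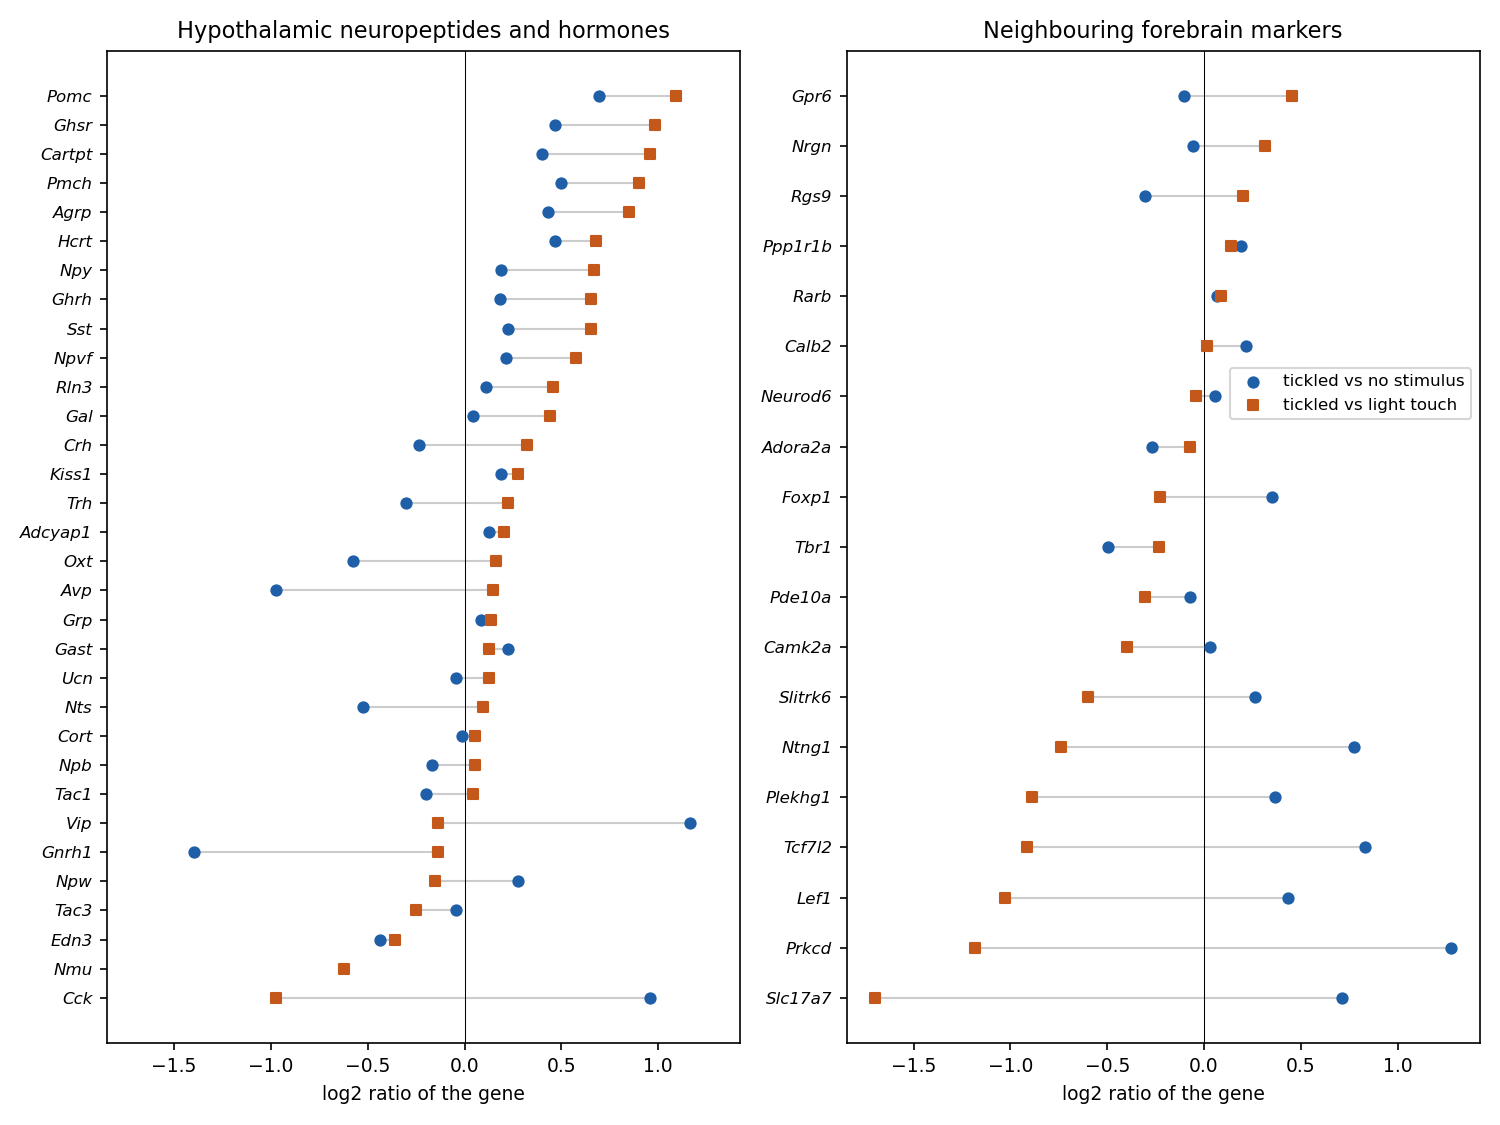
Log2 ratio of each measured hypothalamic neuropeptide gene (left) and neighbouring forebrain marker (right), 1 point per gene and array. Circles are the array of tickled against no stimulus and squares that of tickled against light touch, and a grey line joins the values of a gene. Prkcd, at 2.42 and 0.44, and Slc17a7, at 1.64 and 0.309, lie on opposite sides of 1, and Pomc, at 1.62 and 2.13, on one side.

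Over both arrays, 21 of the 60 medians lay outside the random range, 11 on the no-stimulus array and 10 on the light-touch array, where 3 were expected by chance. Among the 21 were both medians of the nonneural genes expected near background, at 0.12 and 0.15. The random lists were not matched on signal and took genes as independent. The excess over 3 therefore does not by itself show a difference between the groups. A further 15 lists lay inside it on both arrays. These included the stress axis and glucocorticoid response, with medians of -0.001 and -0.007, immediate early genes, with 0.04 and 0.01, and synaptic plasticity and neurotrophin genes, with 0.03 and -0.02. Antioxidant genes had 0.04 and 0.05, apoptosis regulators 0.01 and -0.03, circadian clock genes 0.03 on both, and interferon and MHC genes 0.08 and -0.04. Ribosomal protein genes had -0.01 and 0.01 and oxidative phosphorylation genes 0.00 and -0.01. For astrocytes the medians were 0.07 and 0.04, for microglia 0.04 and 0.00, for endothelial and mural cells 0.08 and -0.03, for choroid plexus -0.04 and -0.03, for skeletal muscle 0.00 and -0.05, and for housekeeping genes -0.06 and -0.04. The lists that stood apart on 1 array had medians of 0.01 (monoamine genes), 0.03 (oligodendrocytes), -0.004 (neurons) and 0.01 (hypothalamic transcription factors) on the no-stimulus array, and of -0.001 (GABA and glutamate), -0.05 (heat shock), 0.11 (ependyma and tanycytes), -0.10 (blood) and 0.07 (meninges) on the light-touch array. In 8 of the 60 pairs the median and the mean differed in sign, and of these the GABA and glutamate list on the no-stimulus array was the 1 that stood apart.

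**Figure D3:**
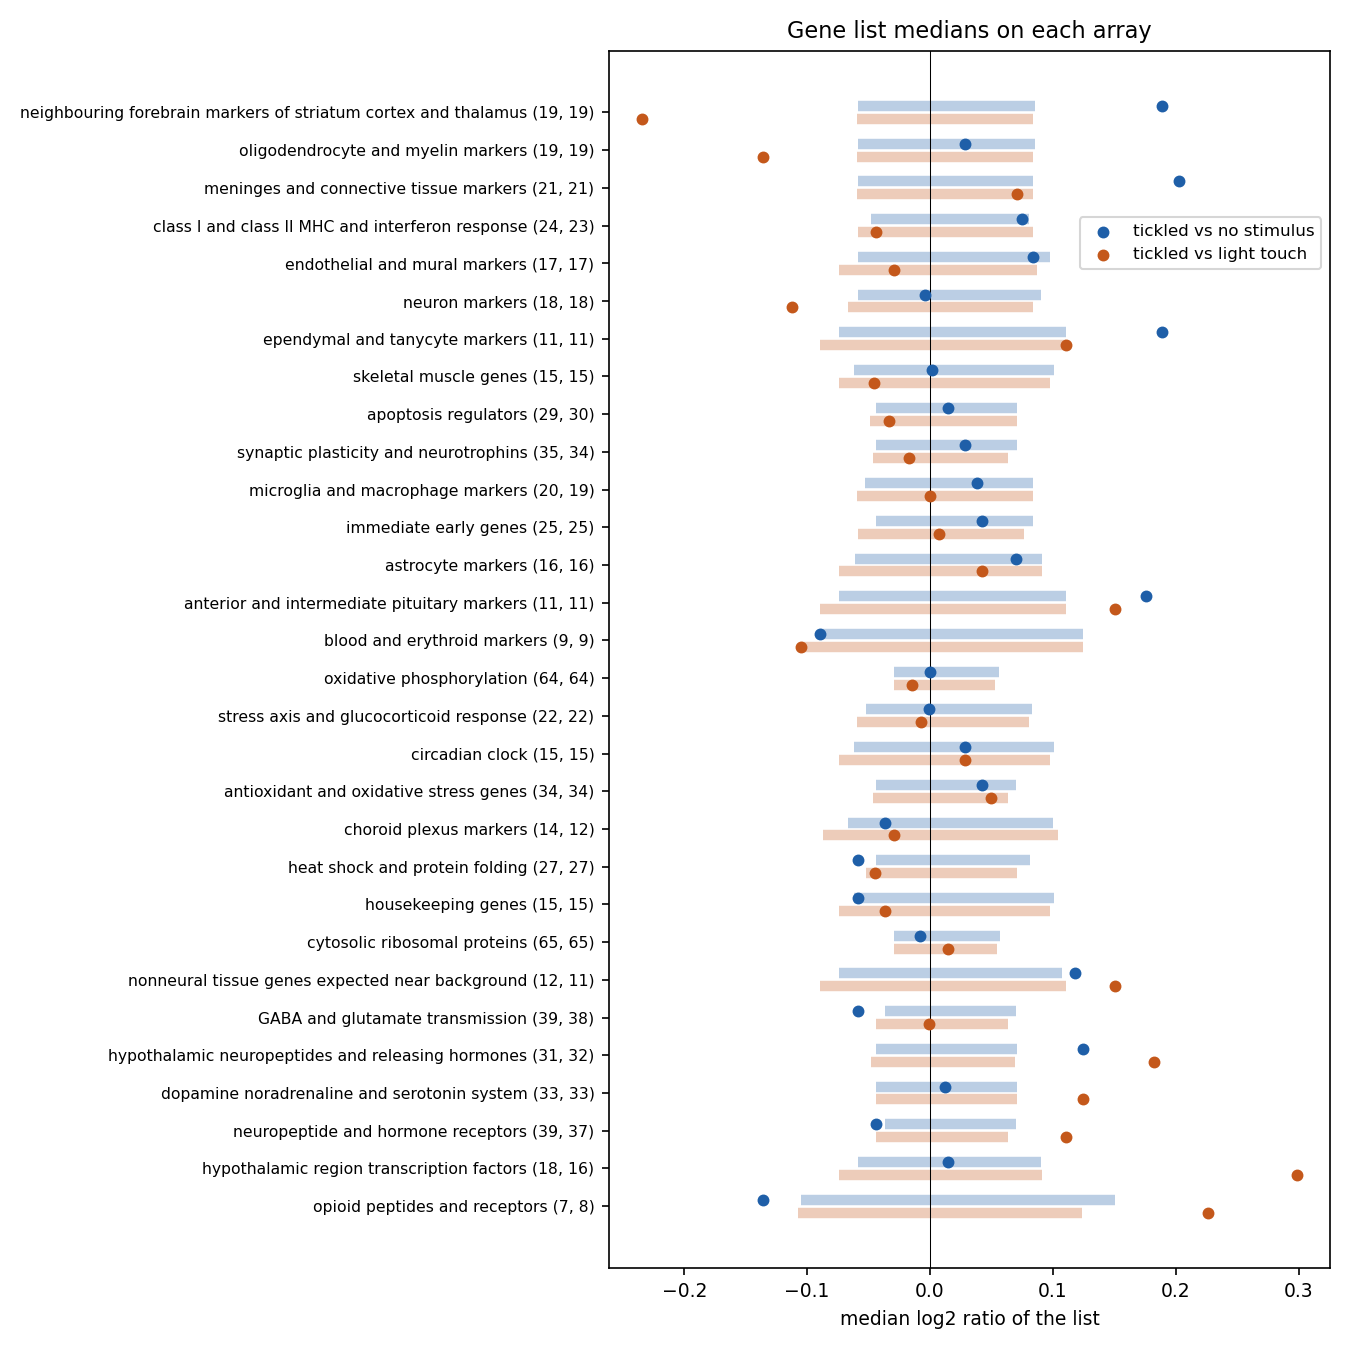
Median log2 ratio of each of the 30 gene lists on each array (points), with the middle 95% of 10000 random lists of the same size (bars). The numbers after each name are the measured genes on the no-stimulus and the light-touch array. The forebrain list lies above its bar on the no-stimulus array, at 0.19, and below it on the light-touch array, at -0.23.

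Few genes lay 2-fold or more from 1 in the same direction on both arrays. Ttr, Slc18a3, Slc5a7, Prpf31 and Ccdc77 had a ratio of 0.5 or less on both arrays. Another 7 genes had a ratio of 2 or more on both, namely Dao at 2.64 and 2.40, Smpdl3b at 2.45 and 2.29, Trim40 at 2.28 and 2.10, Irf2 at 2.10 and 2.09, Mrps10 at 2.15 and 2.05, Serinc2 at 2.04 and 2.03, and Zbtb26 at 2.0 and 2.23. Next in order were Ier3ip1-ps1, Hspa1l and the galanin-like peptide Galp, at 1.93 and 2.14, on the high side, and Pabpn1l, Lhx8, Sostdc1, Cdca8 and Ccn5 on the low side, with Lhx8 at 0.35 and 0.61 and Sostdc1 at 0.55 and 0.65. Each of the 7 high genes had all its probes in the outermost 20% of probe numbers. With the middle 80% of probe numbers 0 genes were at 2 or more on both arrays, and with the local median subtracted 1 was, Dao, although the ratios nearer 1 of these 7 genes moved little, from a median log2 of 1.06 to 0.92. The low genes numbered 5 under both settings. Of these 5 low genes, all had 1 probe per array.

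If the same tickled RNA was put on both arrays, which is not stated, that by itself makes their ratios alike. Independent lists of the observed lengths would share 0.0855 high and 0.0210 low genes. Simulated arms that share the tickled arm gave a mean of 3.68 high genes (0 to 10 over 100 simulations) and 4.11 low genes (0 to 9). Both 7 and 5 lay within these ranges. The arms were drawn from the observed ratios, so the large observed ratios are part of the simulation. It therefore cannot tell how many such genes unchanged groups would give. Across the 11534 genes the log2 ratios correlated with r = 0.33 (bootstrap range over genes 0.28 to 0.38) and rho = 0.35, and 6947 genes (60.2%) lay on the same side of 1. The simulated arms were drawn independently with equal spread, which by itself sets r near 0.50 (0.46 to 0.53 over the simulations). The observed covariance was 0.0133 and the simulated one 0.0204, a difference of -0.00706. The simulated covariance is likewise set by this construction and by the spread of the ratios. Setting the observed r and covariance beside these values therefore does not test whether the tickled RNA was shared. Shared tickled RNA may give part of the likeness of the arrays, but other sources are common to both whether or not it was shared. Both arrays had the tickled group in Cy5, and on both the ratios followed the probe number. With the local median subtracted r was 0.24. How much each of these gave was not tested.

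By difference of the 2 arrays, light touch was set indirectly against no stimulus, which holds only if the tickled RNA was the same on both. The largest differences above 0 were those of Chrna3, 22.2-fold, Cga, 8.62-fold, Tshb, 8.41-fold, Shox2, 6.06-fold, and Prkcd, 5.50-fold. Below 0 they were those of Dio3, 5.76-fold, Ttr, 4.88-fold, Slc6a3, 2.78-fold, the cell death kinase Ripk3 and Lama1, both 2.49-fold. The value of Dio3 does not compare like with like, since the probe at 0.21 on the no-stimulus array was empty on the light-touch array, and the probe measured on both gave 0.87 and 2.46. A difference of 2-fold or more was found above 0 for 67 genes and below 0 for 10 genes, and with the middle 80% of probe numbers for 58 and 6 genes. Of the measured forebrain markers, Slc17a7 and all 7 thalamic members, from Prkcd to Calb2, had a difference above 0, and the median of these 8 was 1.49 log2 units. Genes with a ratio of 2 or more on one array and 0.5 or less on the other numbered 6.

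Ratios followed the probe number on both arrays. In 20 equal blocks of probe numbers the median ratio in the first block was 1.06 on the no-stimulus and 1.03 on the light-touch array. It was 0.96 at its lowest on both, and 1.04 and 1.08 in the last block. Ratios also followed the column of the inferred layout. In the block of columns at one edge the median ratio was 1.06 and 1.08, and at the opposite edge 0.97 on both arrays. Probes with a ratio of 2 or more numbered 47 and 49 at the first edge and 2 and 0 at the opposite edge. Leaving out the outermost 20% of probe numbers leaves out no columns, so it does not remove this trend. Of the 26 probes with a ratio of 2 or more on both arrays, 22 (84.6%) lay in the outermost 20% of probe numbers, and of the 6 with a ratio of 0.5 or less on both, 0 did.

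**Figure D4:**
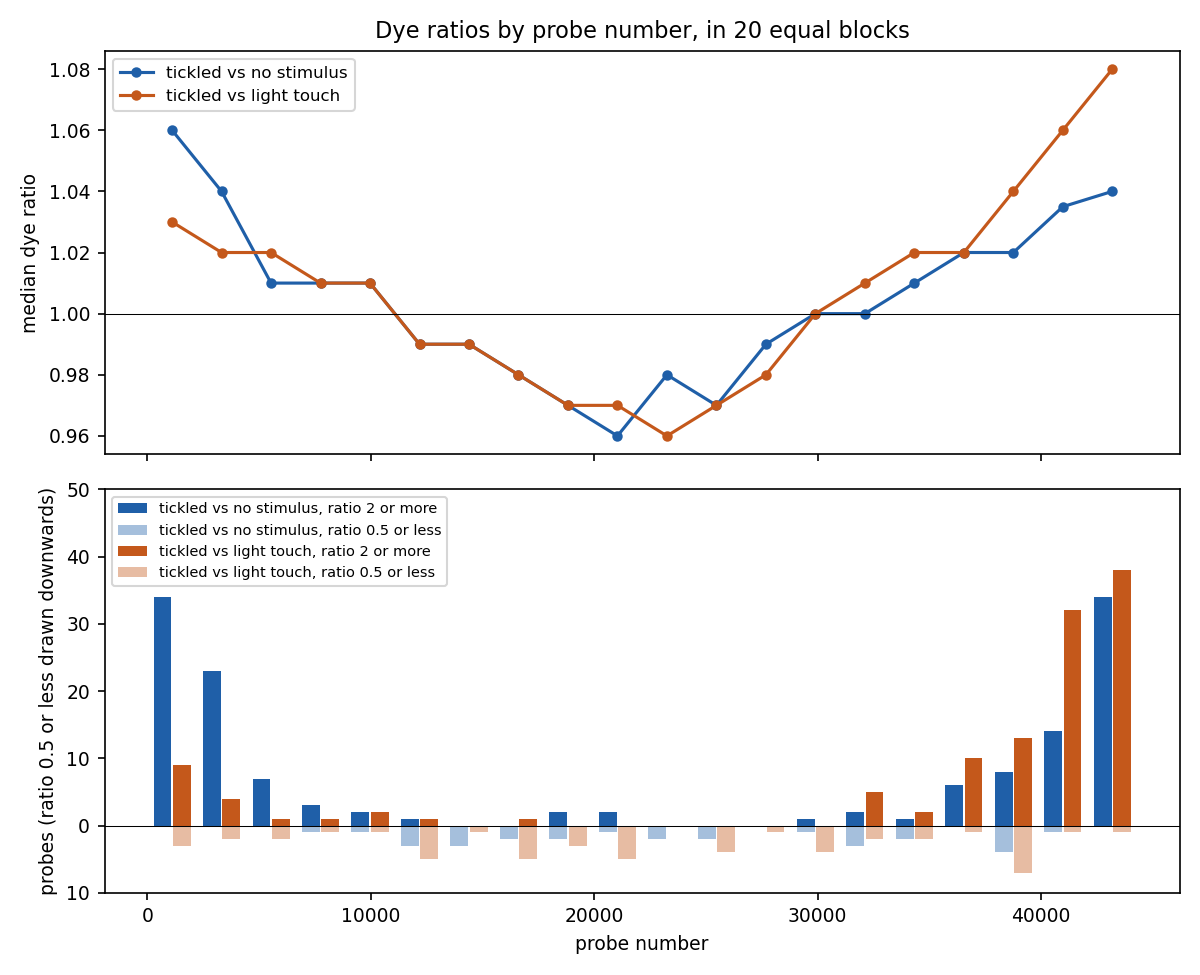
Median dye ratio (top) and number of probes with a ratio of 2 or more (bars up) or 0.5 or less (bars down, in a paler shade) in 20 equal blocks of probe number, for both arrays. On both arrays median ratios lie above 1 toward both ends and are lowest, at 0.96, in the middle, and most probes at 2 or more lie at the ends.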

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

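Except for the markers of thalamus, habenula and pineal tested as one list and the Mtnr1a test, the tests in this part were chosen after the result was seen.

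For 6 genes the ratio was 2-fold or more from 1 on both arrays but on opposite sides, and the difference between the arrays was not tested, since each has no replicate. In log2 units, first against no stimulus and then against light touch, Chrna3 had 2.0 and -2.47, Shox2 1.22 and -1.38, Prkcd 1.28 and -1.18, Grifin 1.12 and -1.22, Ramp3 1.01 and -1.03, and Dio3 -1.23 and 1.30. The values of Dio3 come from different sets of probes.

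Apart from Dio3 and the lens gene Grifin, the opposite genes are ones with strong expression in thalamus or habenula, and thalamic members of the forebrain list went the same way. The local trend of median ratios over the array was small, with block medians from 0.96 to 1.08. Subtracting it could therefore move a difference of this size only a little. The median difference of the 8 measured members, which include Slc17a7 and Prkcd, was 1.52 with the local median subtracted and 1.49 without. These values argue only against that small trend as the whole cause. Subtracting the local median does not test the wider spread of ratios toward the ends of the probe numbers. Different amounts of adjoining thalamic and epithalamic tissue in the dissected RNA may explain the pattern: over 15 markers the median difference was 0.99, with 14 above 0, where random lists ran from -0.09 to 0.09, and without Ramp3, which is also one of the 6 genes, it was 0.87 over 14. That rests on thalamus markers (11 of 14 measured, all above 0, median 1.04, or 1.03 without Ramp3), while habenula and pineal tissue stays open, with a median of 0.17 over the 4 of 13 markers measured. A response to the stimulation cannot be told apart from unequal dissection with 1 array per comparison.

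Tshb and Cga had ratios of 9.08 and 7.18 against no stimulus and 1.08 and 0.833 against light touch. Anterior pituitary tissue is argued against as the whole cause, since growth hormone, its most abundant transcript, had a log2 ratio of 0.79 where Tshb had 3.18. All 11 measured pituitary markers lay above 0 on the no-stimulus array, with a median of 0.18. Some such tissue in the RNA therefore stays open. A single cross-hybridising probe is also argued against, since the lowest of the 3 probes of both genes gave 2.76, and a change of thyrotropin with the stimulation was not tested. The pars tuberalis, a strip of pituitary tissue on the underside of the hypothalamus that makes thyrotropin without growth hormone, may have been taken in unequal amounts, but its melatonin receptor Mtnr1a had 0 probes with a value. Its other markers Eya3, Chga, Sox2, Tbx3 and Cckbr lay near 1, at 1.09, 1.01, 0.98, 1.22 and 1.02, which leaves it open only because the hypothalamus expresses them too and can hide a small share.

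Of the probes at 2 or more on both arrays, 84.6% lay in the outermost 20% of probe numbers, against 19.5% of the probes measured on both. With the local median subtracted, the log2 ratio nearer 0 of the 7 high genes had a median of 0.92 in place of 1.06 (SD 0.10 both times), short of 2-fold by less than that SD, so position stays open as the cause of the high ratios and the local trend took off little of them. For the 5 low genes, which all stayed at 0.5 or less, it was -1.16 in place of -1.25 (SD over genes 0.12 both times). It thus stayed past 2-fold by 0.16, more than that SD but less than the 0.18 by which single probes of a gene spread. The outcome depends on which spread is taken as the bar, and both were chosen after the values were seen. The local trend took off little of the low ratios, but position stays open for them too. Dye bias of the probes could give the high ratios on both arrays as well as the low ones. It cannot be told apart from an effect of tickling, since 0 arrays had tickled RNA in Cy3.

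Probes without a gene name took no part in the comparisons above, and 13 of them had a ratio of 2 or more on both arrays and 1 a ratio of 0.5 or less, of 11771 unnamed probes measured on both. The probe numbered 1507 had ratios of 3 and 3.89, and the probe numbered 39322 had 0.13 and 0.12.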

How the results depend on the processing

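The alternatives on probe position were chosen after the data were seen, and the others before. No paired analysis was possible because each comparison had 1 array and no test. Leaving out replicates was not possible either, and the planned filter on signal level was not run because no level was used. Without signal levels, the number of arrays and the spread between probes are what limits precision.

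Scaling to one spread and keeping genes measured on both arrays left every count within 1.5 times. Centring changed no ratio, and r cannot move under these 3 settings. Without genes beyond 3 median absolute deviations r stayed within its bootstrap range. Counts of genes are given here as ratios above and below 1. At 1.5-fold they were 192 and 43 against no stimulus, 184 and 109 against light touch, 59 and 8 on both arrays, and 187 and 82 for the indirect difference. At 3-fold they were 4 and 1, 0 and 5, 0 and 0, and 20 and 2 (Tshb, Cga, Chrna3, Zfp641 and Ttr; Map3k6, Chrna3, Neurod1, Htr5b and Slc17a7; Dio3 and Ttr for the last). Counted singly, probes numbered 140 and 28, 119 and 51, 26 above on both, and 152 and 25, because several or unnamed probes enter. With the probe of largest absolute mean ratio, 68 and 19 genes passed against no stimulus, 69 above against light touch and 13 above on both, and r was 0.47; with probes singly r was 0.41. Choosing a probe by its mean over both arrays favours probes on the same side of 1 on both, which by itself can raise r and the count on both. The cause of the rise with probes singly was not tested.

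With the middle 80% of probe numbers, the counts above 1 were 12 against no stimulus, 14 against light touch and 0 on both, and 6 genes were below 0 in the indirect difference. Fewer genes are measured there, and this setting leaves out no columns of the inferred layout. With the local median subtracted, 23 were above against light touch and 1 on both, and r was 0.24. The mean log2 ratio of GABA and glutamate genes against no stimulus was 0.026, on the other side of 0 from the median, because its few high members weigh more. Lnx1 against no stimulus was at 0.043 with the middle 80% of probe numbers, which leaves out its low probe. Of other list medians 54 values moved and 365 did not, and of named gene values 20 moved and 736 did not.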

Other observations

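The test of basal forebrain markers was planned before its result was seen, and the tests of choroid plexus markers and of probe position for the neuropeptide genes after.

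The genes named next were chosen after their values were seen and form no tested group. The GABA receptor subunits Gabra4 and Gabrd had ratios of 1.44 and 1.58 against no stimulus and of 0.56 and 0.57 against light touch. The vesicular glutamate transporter Slc17a6 went the same way as Slc17a7, at 1.18 and 0.764, and Slc17a8 the other way, at 0.78 and 1.05, while Gad1, Gad2 and Slc32a1 had 0.82, 0.79 and 0.74 against no stimulus and 1.18, 1.08 and 1.07 against light touch.

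A hypothesis for the low ratio of Ttr is that the RNA of the tickled group held less choroid plexus. The median log2 ratio of the other choroid plexus markers on the no-stimulus array was -0.044 over 9 measured, inside the random range of -0.09 to 0.12, and on the light-touch array -0.06 over 7, inside -0.12 to 0.14. The markers Sostdc1 and F5 were low against no stimulus, at 0.55 and 0.60, and Sostdc1 and Otx2 against light touch, at 0.65 and 0.61, while Folr1, Aqp1 and Clic6 lay near 1 on both arrays. Thus this may be a smaller amount of tissue or may concern Ttr alone, and the data leave it open.

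A second hypothesis, for Slc18a3, Slc5a7, Lhx8 and Ngfr, is that less basal forebrain tissue was taken from tickled animals. The median of the mean log2 ratio over 6 of 9 further markers was 0.00038, where random lists ran from -0.09 to 0.12. By the rule set before the result was seen, a median inside the random range counts against this hypothesis. The test is weak, however. The markers that would best decide it, Chat and Gbx1, had no value on either array (0 of 2), and the 6 that did are also expressed elsewhere in the brain, so a difference in basal forebrain tissue could not be excluded.

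For the neuropeptide genes on the light-touch array, the position of the probes on the array is argued against as the cause of the high median, since the list stayed at percentile 100 of random lists with the local median subtracted. On the same array hypothalamic transcription factors had a median of 0.30 and forebrain markers one of -0.23, so unequal dissection stays open for the peptide genes. On the no-stimulus array, where the peptide median was 0.12, these lists had 0.01 and 0.19.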
